A study of Homo sapiens with 12 samples.

How the data were processed

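The data were Affymetrix human expression arrays of 54675 probe sets, hybridised with biotin-labelled cRNA made from total RNA of Sk-hep1 cells, an established human liver cell line that the labels describe as an endothelial-type adenocarcinoma from ascites. There were 12 arrays in 4 groups of 3: growth medium (GM, based on DMEM) or high-fat medium (HFM, based on DMEM/F12) for 12 or 24 hours. The fat in HFM is not given in the sources used here, and the basal medium differed as well. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

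The values are on the log2 scale and were made by the authors with GCRMA, per the submitters' processing notes, which corrects background, normalises and summarises each probe set. The GCRMA version and any filter are not given in the sources used here. The number of arrays limits the precision.

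Of the probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 had none. Probe sets with several symbols or none were named after no gene. Entrez identifiers of 41043 probe sets were matched to the reference, and 0 symbols changed. Each of 19775 genes was represented by its probe set with the highest mean. Genes at log2 4 or more on at least 3 arrays were tested, which left 13130. Of 6477 tested genes with several probe sets, 4264 were called at 12 hours and 4175 at 24 hours, and 344 and 865 of these had another probe set called in the opposite direction.

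A linear model with 4 group means was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). HFM was compared with GM at 12 hours, at 24 hours and over both times, the HFM effect was compared between times, and 24 hours was compared with 12 hours in each medium. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and errors beside log2 changes are standard errors with n = 3 arrays per group. All gene p-values below are from limma with this adjustment.

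A set of 27 gene lists was fixed before the data were examined. It was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares the members of a list with the other genes tested, so a called list is higher or lower relative to those genes. The hepatocyte, leukocyte and epithelial lists hold markers of other cell types. Lists share some members, such as TXNIP in the PPAR and FOXO lists and VLDLR in the PPAR and ATF4 lists. Camera was repeated with a correlation estimated from the data. Named genes followed a rule fixed at the same time. It took the 8 largest rises and 8 largest falls at 12 and at 24 hours among called genes with a mean of log2 6 or more in the higher group and no overlap between arrays, up to 3 called members of each list, a short list of metabolic genes whatever their values, and the 5 largest rises and falls for the difference between times and for each time contrast. A further gene of the short list and 1 further array control are not reported here.

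The pipeline was tested on simulated data, with 200 changed genes in each of 20 simulations. For HFM against GM at 12 hours among 13130 genes, 19.5% of genes changed by log2 0.25 were recovered, 88.5% at 0.5, 99.9% at 1 and 100% at 2, and 4.1% of calls were unchanged genes. For HFM against GM at 24 hours among 13130 genes, these values were 17.7%, 87.9%, 99.4%, 100% and 4.7%. The simulated noise was independent between genes and few genes changed, whereas 61.9% of genes were called at 12 and 58.1% at 24 hours in the data. These shares therefore describe the simulated setting and not the error rates of the real comparisons.

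Alternatives were another filter or none, the mean of a gene's probe sets, all probe sets, leaving out cross-hybridising probe set types, centring each array on the median of its tested genes, a repeated quantile normalisation, a robust trended eBayes, only the compared groups in the fit, a replicate block, fry, a 2-fold minimum and leaving out each array. A term for the hybridisation control class of the arrays was added after seeing the data. Only HFM at 12 hours holds both classes, so with this term HFM at 12 hours is compared with GM through 1 array. After this HFM 12-hour replicate 1 was singled out among the arrays left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.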

Results

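Gene expression was measured on 12 arrays of Sk-hep1 cells, with 3 arrays each for GM and HFM at 12 and 24 hours. The design asks how incubation in a high-fat environment changes the transcriptome of these cells. The median of the probe set values per array lay between 4.05 and 4.09 on the log2 scale. The first principal component held 69.6% of the variance and the second 16.8%. Arrays of a group correlated at a mean r across genes of 0.998 for GM at 12 hours, 0.994 for HFM at 12 hours, 0.998 for GM at 24 hours and 0.998 for HFM at 24 hours. HFM arrays at 12 hours had a mean r of 0.990 with GM arrays at 24 hours and 0.980 with GM arrays at 12 hours.

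Control probe sets differed between groups. The difference between the 3' and 5' probe sets of ACTB, a cytoskeletal gene used as a control of RNA integrity, was 0.89 ± 0.03 (SD, n = 3) in GM and 0.84 ± 0.13 in HFM at 12 hours, and 1.07 ± 0.05 in GM and 1.58 ± 0.06 in HFM at 24 hours, in log2 units. For GAPDH, a glycolytic gene used the same way, it was 0.16 ± 0.02 in GM and 0.27 ± 0.03 in HFM at 24 hours. Both differences at 24 hours had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. The hybridisation controls, which are spiked into the hybridisation and do not come from the cells, were higher on the 3 GM arrays and 1 HFM array at 12 hours than on the other 8 arrays.

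**Figure D1:**
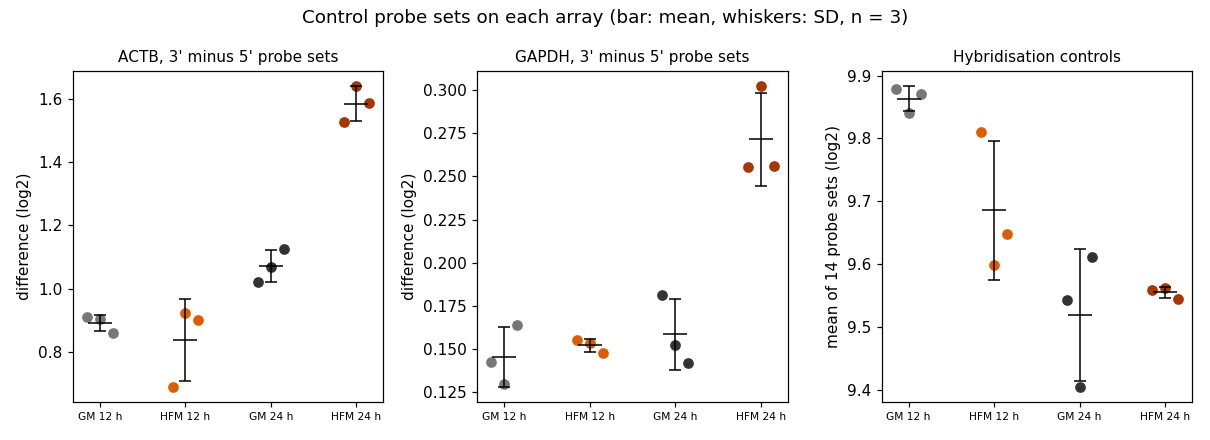
Control probe sets on each array. The left and middle panels give the log2 difference between 3' and 5' probe sets of ACTB and GAPDH and the right panel the mean log2 value of 14 hybridisation control probe sets; points are arrays, bars means and whiskers SD of 3 arrays, and the ACTB difference of HFM at 24 hours (mean 1.58) lies above that of the other groups.

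In HFM at 12 hours, NF-kappaB and immediate early genes were lower than in GM as sets, and FOXO targets and endoplasmic reticulum stress genes were higher. These set calls rest on the preset correlation, and 0 of 27 lists passed in camera with an estimated correlation (2 lists at an unadjusted p under 0.05; fry called 20). IL6, an inflammatory cytokine, changed by -1.85 ± 0.11 (SE, adjusted p = 1.8e-07) on the log2 scale, from a mean level of 8.88 ± 0.05 (SD, n = 3) in GM to 7.03 ± 0.24 in HFM. DUSP4, a phosphatase that switches off MAP kinases, changed by -1.95 ± 0.11 (SE, adjusted p = 8.8e-08). HMGCS1, the enzyme that makes HMG-CoA for cholesterol synthesis, rose by 1.43 ± 0.09 (SE, adjusted p = 1.7e-07), and INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum, rose by 1.60 ± 0.10 (SE, adjusted p = 1.9e-07).

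Of 13130 genes, 8123 were called at 12 hours by limma, 3789 higher and 4334 lower in HFM. Of these, 286 differed by at least 2-fold, 255 higher and 31 lower. The groups did not overlap in 63.6% of genes, against 10% by chance for 3 against 3. The median log2 change of all genes was -0.07. Of the higher genes, 3080 also rose from 12 to 24 hours in GM, against 1114 expected for independent lists. Of the lower genes, 3598 also fell in GM over that time, against 1757 expected. Both comparisons use the GM arrays at 12 hours, and a deviation common to those arrays would enter both. The genes and lists called at 12 hours therefore cannot be assigned to the medium alone.

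The genes with the largest rises were MIR100HG at 2.01, DUSP5P1 at 2.00, CLK1 at 1.98, RUFY2 at 1.86, VMP1 at 1.83, MINCR at 1.79, GOLGA8A at 1.67 and RUFY3 at 1.64. CLK1 is a kinase of splicing factors and VMP1 a membrane protein of autophagosome formation. The largest falls after DUSP4 and IL6 were FAM43A at -1.46, the neutrophil chemokines CXCL8 at -1.43 and CXCL1 at -1.42, the ERK phosphatase DUSP6 at -1.40, the pattern recognition molecule PTX3 at -1.26 and the ribosomal RNA precursor RNA45SN5 at -1.23.

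Among NF-kappaB and inflammatory cytokine genes, 4 of 24 rose, 17 fell and 3 did not pass the test, and the counts were the same adjusted over the list alone. The list was lower as a set (camera adjusted p = 0.0019; adjusted p = 0.54 with an estimated correlation). Among immediate early and serum response genes, 3 of 30 rose, 21 fell and 6 did not pass the test, and the counts were the same adjusted over the list alone. SPRY2, an inhibitor of receptor tyrosine kinase signalling, changed by -1.18. This list was also lower (camera adjusted p = 0.00073; adjusted p = 0.202 with an estimated correlation).

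Of the endoplasmic reticulum chaperone and unfolded protein response genes, 17 of 30 rose, 1 fell and 12 did not pass the test, and the counts were the same adjusted over the list alone. The stress sensor ERN1 rose by 0.85 and the oxidase ERO1B by 0.80. Without HFM replicate 1, 18 of the list rose and 6 fell. ATF6, another sensor, rose by 0.87, although 1 of its probe sets was called in the opposite direction. The list was higher (camera adjusted p = 0.0084; adjusted p = 0.54 with an estimated correlation).

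FOXO targets also moved up, and 13 of 22 rose, 3 fell and 6 did not pass the test, and the counts were the same adjusted over the list alone (camera adjusted p = 0.0071; adjusted p = 0.49 with an estimated correlation). ARRDC4, an arrestin-domain protein, rose by 1.46, its relative TXNIP, which restrains glucose uptake, by 1.18, and the repressor BCL6 by 0.96. Epithelial markers were lower as a set, and 1 of 12 rose, 7 fell and 4 did not pass the test, against 1 up and 9 down adjusted over the list alone (camera adjusted p = 0.045; adjusted p = 0.68 with an estimated correlation). Their largest falls were SPINT2 at -1.08, ELF3 at -0.90 and KRT19 at -0.70. The epithelial list was included as one of another cell type, and the cause of its call was not tested. Without HFM replicate 1 the adjusted p was 0.0018 for FOXO targets and 0.053 for epithelial markers.

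Lipid metabolism lists did not pass the set test at 12 hours, although single members changed. Among cholesterol synthesis and uptake genes, 7 of 21 rose, 7 fell and 7 did not pass the test, and the counts were the same adjusted over the list alone (camera adjusted p = 0.41), and the sterol carrier STARD4 rose by 1.61. Their median was -0.0047 while the mean was 0.27 and the test pointed up. Of fatty acid synthesis and desaturation genes, 8 of 18 rose, 6 fell and 4 did not pass the test, and the counts were the same adjusted over the list alone (camera adjusted p = 0.499). SCD, which introduces a double bond into saturated fatty acids, rose by 0.98 ± 0.04 (SE, adjusted p = 3.1e-08), and the elongases ELOVL7 and ELOVL6 rose by 0.56 and 0.51. This list had a median of -0.03, a mean of 0.08 and a test that pointed up. FASN, the fatty acid synthase, stood at 0.02 (adjusted p = 0.79).

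Of fatty acid beta-oxidation genes, 6 of 25 rose, 11 fell and 8 did not pass the test, and the counts were the same adjusted over the list alone (camera adjusted p = 0.499). The peroxisomal oxidases ACOX2 and ACOX3 changed by -0.78 and -0.77, and ACAA1, a peroxisomal thiolase, by -0.66. CPT1A, which admits fatty acids to mitochondria, stood at -0.11 (adjusted p = 0.15). Among lipid droplet and triglyceride turnover genes, 5 of 28 rose, 13 fell and 10 did not pass the test, against 5 up and 14 down adjusted over the list alone (camera adjusted p = 0.27). G0S2, an inhibitor of triglyceride lipase, changed by -0.98, AUP1 by -0.74 and TMT1B by -0.70. PLIN2, a lipid droplet coat protein, rose by 0.19 ± 0.06 (SE, adjusted p = 0.019).

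PPAR targets at 12 hours were 7 up, 6 down of 21 (camera adjusted p = 0.59). TXNIP rose by 1.18, VLDLR, a lipoprotein receptor, by 0.81 and PDK4, which inhibits pyruvate dehydrogenase, by 0.48. CYP4A11 changed by -0.58. ANGPTL4, an inhibitor of lipoprotein lipase, changed by -0.44. LXR targets and cholesterol efflux genes were 2 up, 2 down of 11 (camera adjusted p = 0.95), with ABCA1, a cholesterol exporter, at 0.24, NR1H3 at -0.67 and NPC1 at 0.30, of which NPC1 had a probe set called in the opposite direction. The LXR median was -0.01 and the mean -0.04, whereas the test pointed up.

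The remaining lists did not pass the set test at 12 hours. ATF4 and amino acid response genes were 8 up, 17 down of 36 (8 up and 18 down adjusted over the list alone; camera adjusted p = 0.499), with rises of DDIT3 at 1.12 and CEBPG at 0.69 and a change of ASNS, asparagine synthetase, of -0.13. Cell cycle and DNA replication genes were 18 up, 15 down of 50 (camera adjusted p = 0.59), with HMMR at 1.27, CENPF at 0.95 and the replication licensing factor CDT1 at -1.11. Hypoxia response and glycolysis genes were 12 up, 9 down of 36 (camera adjusted p = 0.21), led by the glucose transporter SLC2A3 at 1.14, P4HA1 at 1.10 and KDM3A at 1.04. Interferon-stimulated genes were 2 up, 11 down of 24 (camera adjusted p = 0.067), with IRF1 at -1.09, ISG20 at -0.70 and OAS1 at -0.65; without HFM replicate 1 their adjusted p was 0.0304.

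p53 targets were 12 up, 6 down of 25 (camera adjusted p = 0.22), including TP53I3 at -0.82, TP53INP1 at 0.80 and the death receptor FAS at 0.76. NRF2 targets were 9 up, 5 down of 30 (8 up and 5 down adjusted over the list alone; camera adjusted p = 0.52), with TXNRD1 at 0.63, the cystine transporter SLC7A11 at 0.61 and UGDH at 0.56, while HMOX1, heme oxygenase, stood at -0.12 (adjusted p = 0.24). Metallothionein and zinc response genes were 3 up, 1 down of 11 (3 up and 0 down adjusted over the list alone; camera adjusted p = 0.29), with the zinc exporter SLC30A1 at 0.64, SLC30A2 at -0.28 and SLC39A10 at 0.28, and MT2A at 0.04 (adjusted p = 0.45). Autophagy and lysosome genes were 6 up, 13 down of 33 (camera adjusted p = 0.52), with FLCN at -0.55, ATP6V0D1 at -0.50 and GABARAPL1 at 0.47.

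Extracellular matrix and mesenchymal genes were 15 up, 9 down of 42 (camera adjusted p = 0.59), with the protease PLAU at -0.82, TGFB2 at 0.81 and the collagen COL1A1 at -0.74, of which COL1A1 had a probe set called in the opposite direction. Endothelial markers were 1 up, 8 down of 14 (camera adjusted p = 0.12), with ROBO4 at -1.02, ICAM2 at -0.93 and NOS3 at -0.68. Hepatocyte markers were 1 up, 1 down of 11 (0 up and 1 down adjusted over the list alone; camera adjusted p = 0.62), with TTR at -0.38 and CYP3A4 at 0.21. Leukocyte markers were 0 up, 4 down of 9 (camera adjusted p = 0.25), with CD14 at -0.78, CORO1A at -0.43 and CD79A at -0.39. Oxidative phosphorylation genes were 8 up, 15 down of 39 (camera adjusted p = 0.59), with NDUFS7 at -0.53, ATP5PB at 0.47 and UQCRC1 at -0.47. Cytosolic ribosomal protein genes were 6 up, 5 down of 33 (3 up and 2 down adjusted over the list alone; camera adjusted p = 0.95), with RPS24 at 0.36, RPL11 at 0.23 and RPS9 at -0.22. Heat shock genes were 5 up, 4 down of 19 (camera adjusted p = 0.81), with HSPA4L at 1.08, HSP90AA1 at 0.76 and DNAJB1 at -0.51. Ubiquitous control genes were 5 up, 5 down of 24 (4 up and 4 down adjusted over the list alone; camera adjusted p = 0.95), with the transferrin receptor TFRC at -1.001, CHMP2A at -0.27 and SNRPD3 at 0.26.

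After centring each array, the balance at 12 hours turned to more falls than rises among cell cycle (16 rose, 18 fell), extracellular matrix (12 rose, 13 fell), ribosomal protein (3 rose, 7 fell), heat shock (4 rose, 5 fell), cholesterol (7 rose, 8 fell) and ubiquitous control genes (4 rose, 6 fell). After repeated quantile normalisation it did so among cell cycle (15 rose, 18 fell), extracellular matrix (10 rose, 15 fell), heat shock (4 rose, 6 fell), cholesterol (7 rose, 8 fell) and ubiquitous control genes (5 rose, 8 fell), NRF2 targets (7 rose, 9 fell), LXR targets (2 rose, 3 fell) and hepatocyte markers (0 rose, 1 fell). Without HFM replicate 1, NRF2 targets had 11 rises and 11 falls, extracellular matrix genes 17 and 15, oxidative phosphorylation genes 8 and 22, interferon-stimulated genes 3 and 16, cholesterol genes 7 and 8, ribosomal protein genes 7 and 7, heat shock genes 7 and 7, ubiquitous control genes 6 and 9 and hepatocyte markers 0 and 2. With a term for the hybridisation control class, HFM replicate 1 was the only HFM array left in the 12-hour comparison. That gave 7979 calls, 4409 higher and 3570 lower, with 355 higher and 94 lower by at least 2-fold, and rises and falls of 10 and 6 for autophagy, 12 and 9 for oxidative phosphorylation, 8 and 7 for beta-oxidation, 10 and 5 for cholesterol, 9 and 6 for ubiquitous control and 7 and 8 for ribosomal protein genes and 4 and 1 for LXR targets.

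In HFM at 24 hours, transcripts of the endoplasmic reticulum stress response, FOXO targets and extracellular matrix genes were higher than in GM, and almost all measured cell cycle genes were lower. DDIT3, a stress-induced transcription factor, rose by 3.22 ± 0.09 (SE, adjusted p = 1.4e-10), from a mean level of 8.28 ± 0.11 (SD, n = 3) in GM to 11.49 ± 0.07 in HFM. TXNIP rose by 3.14 ± 0.07 (SE, adjusted p = 2.6e-11) and HMGCS1 by 2.75 ± 0.09 (SE, adjusted p = 4.0e-10). MCM10, a DNA replication initiation factor, changed by -1.80 ± 0.05 (SE, adjusted p = 2.2e-10). These changes went with the larger 3' to 5' difference of ACTB and GAPDH in HFM at 24 hours.

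At 24 hours, limma called 7623 genes, 2700 higher and 4923 lower in HFM. Of these, 983 differed by at least 2-fold, 300 higher and 683 lower. The groups did not overlap in 68.7% of genes, against 10% by chance. The median log2 change of all genes was -0.08, and centring each array on its median moved it to 0.10 and gave 8286 calls, 4852 higher and 3434 lower.

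Besides DDIT3 and TXNIP, the largest rises were SNORA72 at 3.60, the histone gene H2BC21 at 3.47, RPS16P5 at 3.33, SLC2A3 at 3.18, TAF1D at 3.02 and LATS2, a kinase of the Hippo pathway, at 2.82. The largest falls were NCOA5 at -3.67, LCMT2 at -3.67, ZNF804A at -3.11, STARD13 at -2.92, HYLS1 at -2.89, the translation initiation factor EIF5 at -2.86, CYREN at -2.86 and ZC3H12C at -2.78. STARD13 had a probe set called in the opposite direction.

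**Figure D2:**
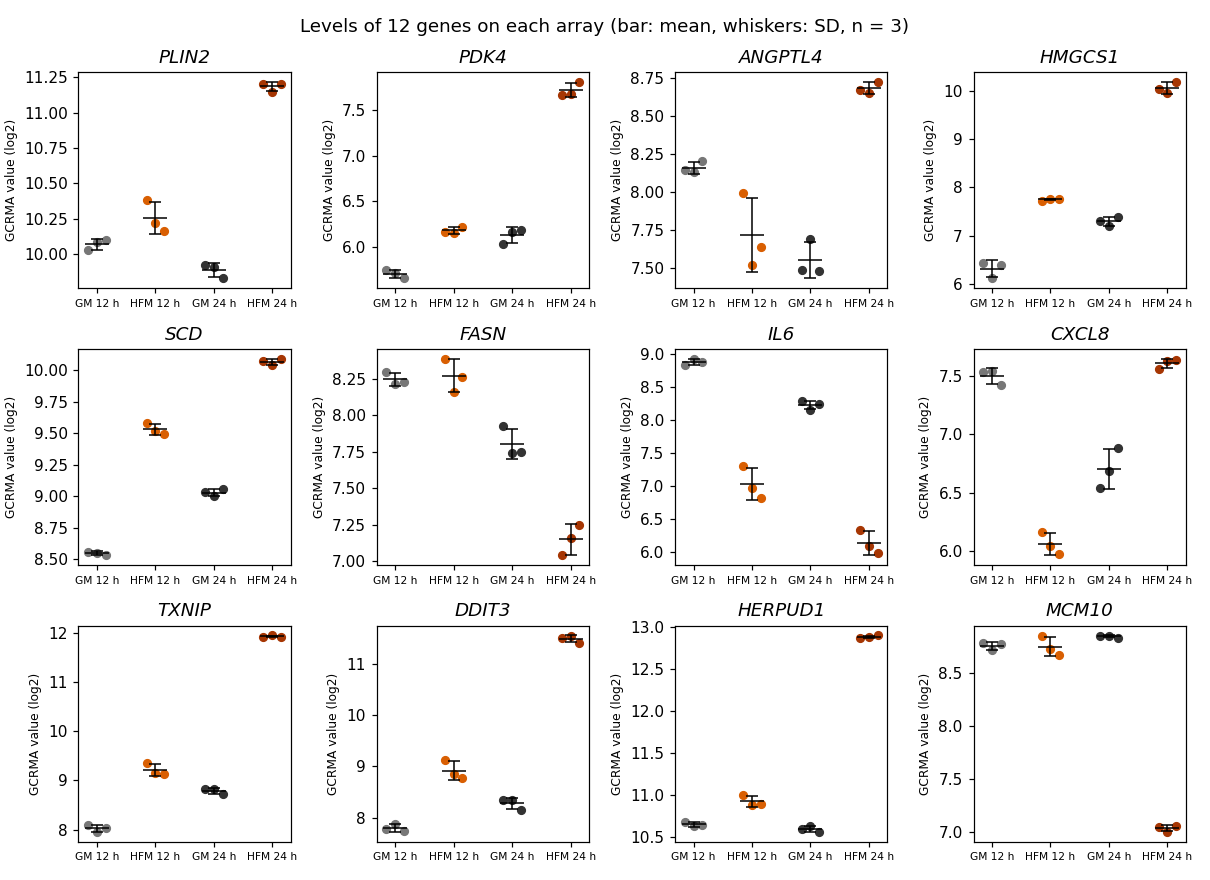
GCRMA values (log2) of 12 genes on each array in GM and HFM at 12 and 24 hours. Points are arrays, bars are means and whiskers SD of 3 arrays; DDIT3 has a mean of 11.49 in HFM at 24 hours against 8.28 in GM, and IL6 a mean of 6.13 against 8.23.

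Of the endoplasmic reticulum chaperone and unfolded protein response genes, 27 of 30 rose, 0 fell and 3 did not pass the test, and the counts were the same adjusted over the list alone. DNAJB9, a co-chaperone, rose by 2.39, HERPUD1, a component of protein degradation at this organelle, by 2.28, and ERN1 by 1.73. The list was higher (camera adjusted p = 2.8e-13; 0.02 with an estimated correlation). In the cell cycle and DNA replication list, 0 of 50 rose, 47 fell and 3 did not pass the test, against 0 up and 48 down adjusted over the list alone. E2F2, a transcription factor of S-phase genes, changed by -1.61, and the phosphatase CDC25A by -1.59. This list was lower (camera adjusted p = 3.0e-11; 0.0046 with an estimated correlation), and after centring each array 40 fell and 0 rose.

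FOXO targets were higher, and 16 of 22 rose, 1 fell and 5 did not pass the test, against 17 up and 1 down adjusted over the list alone (camera adjusted p = 1.2e-09; 0.012 with an estimated correlation), with BCL6 at 2.30 and ARRDC4 at 1.64. Extracellular matrix and mesenchymal genes were higher, and 26 of 42 rose, 4 fell and 12 did not pass the test, and the counts were the same adjusted over the list alone (camera adjusted p = 7.6e-09; 0.0046 with an estimated correlation). The growth factor TGFB2 rose by 1.78, the matrix protein POSTN by 1.73 and the collagen cross-linking enzyme LOX by 1.29.

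Another 5 lists were higher relative to the other genes with the preset correlation and did not pass with an estimated one. Hypoxia response and glycolysis genes were 23 up, 1 down of 36 (camera adjusted p = 5.5e-08; adjusted p = 0.061 with an estimated correlation), including P4HA1 at 1.70 and PDK1, a kinase of pyruvate dehydrogenase, at 1.66. p53 targets were 16 up, 5 down of 25 (camera adjusted p = 7.3e-05; adjusted p = 0.14 with an estimated correlation), with the cytokine GDF15 at 1.84, GADD45B at 1.55 and GADD45A at 1.41. Autophagy and lysosome genes were 19 up, 6 down of 33 (camera adjusted p = 0.00043; adjusted p = 0.59 with an estimated correlation), with RRAGD at 0.83, PSAP at 0.75 and LAMP2 at 0.71. ATF4 and amino acid response genes were 12 up, 10 down of 36 (camera adjusted p = 0.015; adjusted p = 0.59 with an estimated correlation), with ATF3 at 2.11 and ASNS at 0.49. PPAR targets were 8 up, 4 down of 21 (camera adjusted p = 0.023, and adjusted p = 0.32 with an estimated correlation). TXNIP, also in the FOXO list, rose by 3.14, PDK4 by 1.60, VLDLR by 1.31 and ANGPTL4 by 1.13.

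Lipid metabolism lists other than the PPAR targets did not pass at 24 hours. Cholesterol synthesis and uptake genes were 8 up, 6 down of 21 (camera adjusted p = 0.097), with INSIG1 at 2.63 and STARD4 at 1.79, a median of -0.0075 and a mean of 0.34. Fatty acid synthesis and desaturation genes were 4 up, 3 down of 18 (camera adjusted p = 0.25), with SCD at 1.04, FADS3 at 0.73 and FASN at -0.66, a median of -0.0035 and a mean of 0.07; after centring, 9 rose and 1 fell. Fatty acid beta-oxidation genes were 2 up, 11 down of 25 (camera adjusted p = 0.36), with ACOX2 at -1.39, ACOX3 at -1.07 and CPT2, a mitochondrial acyltransferase, at -1.02; after centring, 8 rose and 6 fell. CPT1A stood at -0.14 (adjusted p = 0.079). Lipid droplet genes were 5 up, 9 down of 28 (camera adjusted p = 0.94), with PLIN2 at 1.30, FAF2 at -1.65 and TMT1B at -0.92; after centring, 9 rose and 7 fell. LXR targets were 4 up, 4 down of 11 (camera adjusted p = 0.29), with NR1H3 at -1.18, ABCA1 at 0.82 and the lipoprotein receptor SCARB1 at 0.79.

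Among stress and inflammatory lists at 24 hours, NRF2 targets were 11 up, 9 down of 30 (camera adjusted p = 0.22), with KEAP1, the repressor of NRF2, at -1.18, AKR1C1 at 0.84 and HMOX1 at 0.80. Metallothionein and zinc response genes were 5 up, 2 down of 11 (camera adjusted p = 0.18), with MTF1 at -0.84, SLC39A10 at 0.57, MT1E at 0.36 and MT2A at -0.0053 (adjusted p = 0.93). NF-kappaB and cytokine genes were 10 up, 5 down of 24 (camera adjusted p = 0.13), with IL6 at -2.10, NFKBIZ at 1.44 and CXCL8 at 0.90. Immediate early genes were 12 up, 13 down of 30 (camera adjusted p = 0.24; after centring, 15 rose and 11 fell), with the mRNA decay factor ZFP36 at 1.93 and DUSP5 at 1.77. Interferon-stimulated genes were 8 up, 4 down of 24 (camera adjusted p = 0.22), with IFIT2 at 0.85, IRF1 at -0.78 and IFIT1 at -0.75. Heat shock genes were 2 up, 10 down of 19 (camera adjusted p = 0.13), with DNAJB6 at -1.83, DNAJA1 at -1.37 and BAG3 at -1.22.

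Endothelial markers at 24 hours were 1 up, 3 down of 14 (camera adjusted p = 0.89; after centring, 5 rose and 2 fell), with ROBO4 at -0.78, EPAS1 at 0.61 and NOS3 at -0.46. Hepatocyte markers were 2 up, 3 down of 11 (camera adjusted p = 0.58; after centring, 5 rose and 1 fell), with TDO2 at -0.87, SERPINA1 at 0.54 and AFP at -0.52. Leukocyte markers were 2 up, 2 down of 9 (camera adjusted p = 0.59), with CORO1A at -0.53, CD14 at -0.39 and CD74 at 0.34. Epithelial markers were 1 up, 4 down of 12 (camera adjusted p = 0.796; after centring, 6 rose and 2 fell), with SPINT2 at -0.77, ELF3 at -0.55 and MUC1 at 0.31. Oxidative phosphorylation genes were 2 up, 14 down of 39 (1 up and 14 down adjusted over the list alone; camera adjusted p = 0.58; after centring, 17 rose and 3 fell), with ATP5MC3 at -0.46, ATP5F1D at -0.45 and NDUFS7 at -0.31, which had a probe set called in the opposite direction. Cytosolic ribosomal protein genes were 1 up, 0 down of 33 (0 up and 0 down adjusted over the list alone; camera adjusted p = 0.45; after centring, 31 rose and 0 fell), with RPL14 at 0.13. Ubiquitous control genes were 5 up, 10 down of 24 (6 up and 11 down adjusted over the list alone; camera adjusted p = 0.91; after centring, 11 rose and 5 fell), with TBP at -0.67, VCP at -0.47 and POLR2A at -0.43.

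After centring each array, rises and falls at 24 hours were 21 and 5 for ATF4 genes, 12 and 3 for PPAR targets, 16 and 4 for interferon-stimulated genes, 15 and 6 for NRF2 targets, 14 and 5 for NF-kappaB genes, 7 and 1 for metallothionein genes, 10 and 6 for cholesterol genes and 5 and 2 for LXR targets. They were 28 and 0 for endoplasmic reticulum stress genes, 19 and 1 for FOXO targets, 31 and 1 for extracellular matrix genes, 30 and 1 for hypoxia genes, 18 and 5 for p53 targets, 25 and 5 for autophagy genes, 5 and 7 for heat shock genes and 2 and 1 for leukocyte markers. Repeated quantile normalisation gave 3 rises and 16 falls for oxidative phosphorylation, 3 and 12 for beta-oxidation and 5 and 9 for lipid droplet genes. It gave 5 and 11 for ubiquitous control and 2 and 2 for ribosomal protein genes. Endothelial markers had 1 and 3, epithelial markers 2 and 4 and hepatocyte markers 2 and 3. Except for ribosomal protein genes, these lists kept the balance they had without rescaling. Median, mean and test differed in sign at 24 hours for several lists that did not pass. The test pointed up where median and mean were -0.05 and -0.09 for endothelial markers, -0.04 and -0.06 for ubiquitous control genes, -0.02 and -0.0022 for ribosomal protein genes, 0.06 and -0.04 for hepatocyte markers, 0.00047 and -0.03 for leukocyte markers and 0.06 and -0.07 for epithelial markers.

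**Figure D3:**
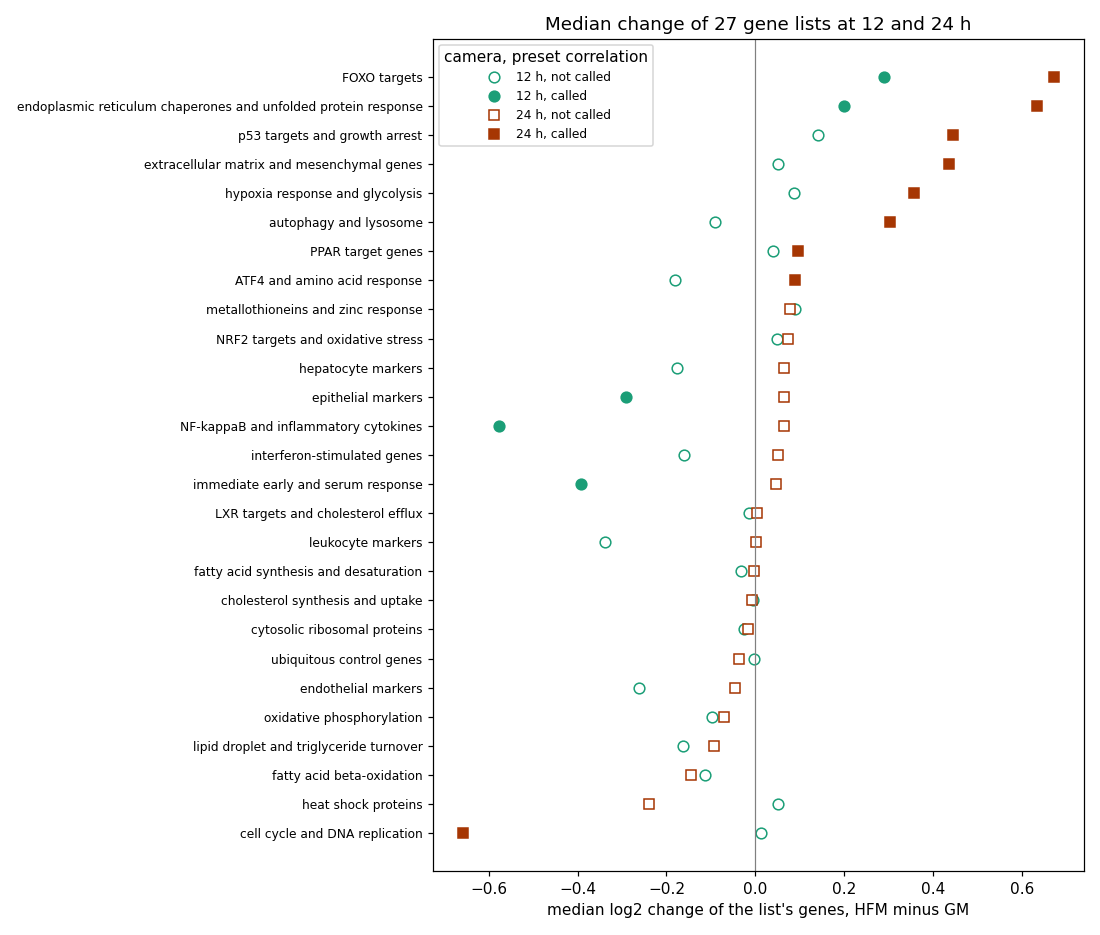
Median log2 change, HFM minus GM, of the genes of 27 lists at 12 hours (circles) and 24 hours (squares), filled where camera with the preset correlation called the list. Cell cycle genes have a median of -0.66 at 24 hours and 0.01 at 12 hours; centring each array moved the median of all genes at 24 hours to 0.10 and turned the sign of several medians near 0.

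Over both times, IL6 was lower and HMGCS1, INSIG1, TXNIP and BCL6 were higher in HFM at each time. In total 8478 genes were called for the mean HFM effect by limma, 3322 higher and 5156 lower, and 346 of them by at least 2-fold, 184 higher and 162 lower. After centring each array, 4299 were higher and 3971 lower. Called genes overlapped between times, with 1456 higher at both (779 expected for independent lists, odds ratio 4.06, one-sided Fisher's exact p = 7.54e-212) and 2133 lower at both (1625 expected, odds ratio 2.09, p = 1.44e-83), with genes taken as independent, which they are not. Another 1207 genes were higher at 12 and lower at 24 hours (1421 expected), and 378 the reverse (891 expected). Both counts were below those of independent lists.

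Among genes with a higher HFM effect at 24 than at 12 hours, SNORA72, FOLR1, RPS16P5, H2BC21 and PPP1R15A differed most, by log2 2.68, 2.68, 2.67, 2.55 and 2.50. PPP1R15A is a phosphatase subunit that restores translation after stress, and FOLR1 a folate receptor. Larger differences went the opposite way, with ZNF804A at -3.42, the mitochondrial tRNA methyltransferase subunit TRMT10C at -3.18, HYLS1 at -3.05, EIF5 at -2.99 and FILIP1L at -2.94. By the interaction contrast in limma, 6931 genes differed, 2551 with a higher and 4380 with a lower effect at 24 hours. After centring each array 5068 were higher and 3134 lower, and after repeated quantile normalisation 3487 and 3872. Camera called 15 lists for this difference, 13 up and 2 down, and 4 with an estimated correlation.

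From 12 to 24 hours in GM, CENPE, a kinetochore motor, rose by 2.27, SGO2 by 2.14, CCDC150 by 2.13, HMMR by 2.10 and the kinesin KIF20B by 1.97. The largest falls were the peroxidase PRDX2 at -1.60, SBSN at -1.50, the quinone reductase NQO1 at -1.33, RBM14 at -1.29 and S100A3 at -1.25. Limma called 9182 genes, 3860 higher and 5322 lower at 24 hours, and the median change of all genes was -0.12. All GM arrays at 12 hours were of the higher hybridisation control class and all at 24 hours of the lower. Within GM, time and class therefore cannot be told apart. With the hybridisation control class as a term, estimated from the 3 HFM arrays at 12 hours alone, 3903 were higher and 3486 lower, and 12 genes were called in the opposite direction. Camera called 0 of 27 lists, with 7 at an unadjusted p under 0.05, and fry called 24; cell cycle genes were 19 up, 18 down of 50 (camera adjusted p = 0.41).

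From 12 to 24 hours in HFM, the largest rises were SNORA72 at 3.75, RPS16P5 at 3.74, KIAA0754 at 3.27, H2BC21 at 3.23 and TAF1D at 3.12. The largest falls were LCMT2 at -3.25, NCOA5 at -3.15, HPS6 at -2.90, the steroid dehydrogenase HSD17B1 at -2.90 and the death receptor adaptor FADD at -2.83. Limma called 8290 genes, 2637 higher and 5653 lower at 24 hours, and the median change of all genes was -0.12; after centring each array 5133 were higher and 3790 lower. Camera called 8 lists. Endoplasmic reticulum stress genes were 22 up, 3 down of 30 (adjusted p = 2.8e-09; 0.043 with an estimated correlation), and FOXO targets were 18 up, 1 down of 22 (adjusted p = 3.7e-09; 0.0203 with an estimated correlation). Immediate early genes were 21 up, 7 down of 30 (adjusted p = 1.3e-05; 0.026 with an estimated correlation), and extracellular matrix genes were 22 up, 7 down of 42 (adjusted p = 0.000101; 0.024 with an estimated correlation). Cell cycle genes were 0 up, 42 down of 50 (adjusted p = 1.7e-07; 0.0203 with an estimated correlation). Between the same groups, the mean 3' to 5' difference went from 0.84 to 1.58 for ACTB and from 0.15 to 0.27 for GAPDH. The NF-kappaB, p53 and hypoxia lists were higher with the preset correlation, with an adjusted p = 0.55, 0.26 and 0.55 with an estimated correlation.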

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

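The tests of the shared GM arrays and of the hybridisation control class were chosen after the result was seen, and the zinc finger genes were picked as a group after seeing the data.

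The HFM effect differed between 24 and 12 hours for 6931 genes in limma's interaction contrast. Among gene lists, the median log2 difference, 24 minus 12 hours, was 0.70 for NF-kappaB and cytokine genes (camera adjusted p = 2.7e-05), 0.59 for immediate early genes (4.6e-06), 0.43 for endoplasmic reticulum stress genes (2.7e-07), 0.41 for extracellular matrix genes (2.7e-07) and 0.38 for FOXO targets (4.6e-06). It was 0.37 for epithelial markers (0.015), 0.31 for hypoxia genes (0.00015), 0.28 for autophagy and lysosome genes (0.00012), 0.24 for endothelial markers (0.0204) and 0.24 for interferon-stimulated genes (0.0035). For ATF4 genes it was 0.20 (0.00055), for PPAR targets 0.19 (0.015) and for p53 targets 0.14 (0.0204). Cell cycle genes went the other way at -0.68 (1.1e-09), as did heat shock genes at -0.32 (0.0204). With an estimated correlation the adjusted p was 0.0072 for cell cycle, 0.0072 for extracellular matrix, 0.028 for immediate early genes and 0.04 for FOXO targets, and the other 11 lists did not pass.

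Of 153 named genes, 116 had a called difference between times in limma, and 16 of them were called in opposite directions at 12 and 24 hours. The log2 effect of HFM was higher at 24 hours by 2.34 for CXCL8, 2.25 for DUSP5, 1.58 for ANGPTL4, 1.07 for FADS3, 0.68 for CD74, 0.62 for ASNS, 0.61 for TTR and 0.42 for CHMP2A. The difference was -3.42 for ZNF804A, -2.43 for HMMR, -1.53 for DNAJA1, -1.51 for CENPF, -1.35 for HSPA4L, -0.90 for SLC30A1, -0.64 for ATP5PB and -0.51 for SNRPD3. In control probe sets, the 3' to 5' difference in HFM at 24 hours lay above all GM arrays for ACTB (mean 1.58) and GAPDH (0.271, in log2 units). Among 3914 tested probe sets without a gene symbol, 2131 were called at 24 hours, 1345 higher and 786 lower. Groups of 3 arrays were not tested for outlying samples. HFM 12-hour replicate 1 deviated most from its group. The SD over genes of its difference from the other replicates was 0.288, against at most 0.170 on any other array. The lowest r within HFM at 12 hours was 0.991. Without this array, 8975 genes were called at 12 and 8731 at 24 hours, against 8123 and 7623 with it.

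For comparisons of 3 against 3 arrays, the 10 possible splits are too few for a share under 0.05. In fits of the 6 arrays compared, the real split called 6897 genes at 12 hours, 8352 at 24 hours, 10029 over time in GM and 7299 over time in HFM, and 1 of the 10 splits, the real one, gave as many in each case. The highest of the other splits called 0 genes in each case by limma, with 343, 214, 74 and 131 genes at an unadjusted p under 0.05. For gene lists, the real split called 5 at 12 hours against 3 in the highest other split, and 9 at 24 hours, where 2 of the 10 splits, the real one included, called 9 and the rest 6 to 8. The other split with 9 exchanges replicate 1 between GM and HFM. Each of the other splits sets 2 arrays of a medium and 1 of the other against the reverse, so it still carries part of the medium effect. Over both times, 1 of 100 splits within each time, the real one and 99 drawn of 200 possible, called as many genes as the real 8478, and the highest other called 6931, or 3422 without the split that exchanges GM and HFM at 1 time. For the difference between times, 2 of 100 splits called at least the real 6931. The other of these called 8478, and it exchanges GM and HFM at 1 time, which turns the difference into the mean effect, so that these splits carry real effects. Without it the highest was 4754.

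HFM at 12 hours resembled GM at 24 hours: their log2 changes against GM at 12 hours correlated across genes at r = 0.848 (Spearman 0.837), where unchanged groups simulated against shared GM arrays gave 0.497. The covariance was 0.179 against at most 0.0045 in 100 simulations, and the difference from the simulated mean was 0.174. This argues against independent noise of the shared GM arrays as the whole cause. The simulations held no deviation common to all GM arrays at 12 hours, so they cannot decide whether such a deviation gave the resemblance. The HFM 12-hour array of the GM 12-hour control class had a slope of 0.595 on the GM time change (95% bootstrap interval over genes 0.583 to 0.607), where a class effect predicts about 0. That is 1 array, so the slope does not rule out a part of the control class in this resemblance. HFM arrays at 12 hours also had a mean r of 0.990 with GM at 24 hours against 0.980 with GM at 12 hours, and an exchange of labels between these groups, which would alter every comparison except the difference between times, may be involved and was not tested.

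Cell cycle genes fell at 24 hours in HFM, 47 of 50 with a median of -0.66. After centring each array the median was -0.48, which argues against the scaling of the arrays as the whole cause. For 32 of the genes with several probe sets, the median of the least lowered probe set was -0.31 (95% bootstrap interval over genes -0.51 to -0.14). Taking the highest probe set raises this value whatever the cause, and over all 6477 genes with several probe sets it was 0.13. The interval takes genes as independent and does not measure the spread between arrays. It reaches above the bound of -0.2 set before the test was run. Both 3' end bias from RNA quality and an effect of the medium may therefore be involved.

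Zinc finger genes named ZNF fell at 24 hours in HFM, 203 of 355 with a median of -0.32, and 57 rose (camera adjusted p = 0.001; adjusted p = 0.30 with an estimated correlation). Of 10000 random lists matched on mean level, with genes taken as independent, 0 had a median as low (lowest -0.18). Mean level alone thus did not give such a median in random lists. The group was picked after seeing the data, so this comparison is no test of its fall. The least lowered probe sets had a median of -0.034 (95% bootstrap interval over genes -0.14 to 0.059). Over all 6477 genes with several probe sets it was 0.13. Choosing the least lowered probe set raises the median whatever the cause, so 3' end bias is neither favoured nor excluded. After centring each array the median was -0.14, between the bounds set before the test was run, so the scaling stays open as well.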

How the results depend on the processing

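The tests with the hybridisation control class as a term were chosen after seeing the data. With probe sets in place of genes, 17568 were called at 12 hours, 17324 at 24 hours, 18839 over both times, 15519 for the difference, 19558 over time in GM and 18580 over time in HFM, from more features tested. A log2 change of at least 1 left 286, 983, 346, 1045, 561 and 1004 genes by construction. An estimated correlation left 0 lists at 12 and 4 at 24 hours, fry, which compares no list with other genes, called 20 and 19, and no filter gave 9 lists at 12 hours, the cause of which was not tested. The control class as a term gave 3 lists at 12 hours, from 1 HFM array by construction. Without 1 array, calls ranged from 7169 to 8975 at 12 hours, 6919 to 8731 at 24 hours, 8003 to 9298 over both times, 6204 to 8159 for the difference, 8415 to 10120 over time in GM and 7618 to 8458 over time in HFM. Lists ranged from 4 to 5 and stayed at 9, and the odds ratios of overlap from 3.64 to 4.43 for higher and 1.91 to 2.49 for lower genes. Replicate numbers did not pair the arrays (correlations of deviations -0.064, 0.129 and -0.165 at 12 and 0.255, 0.0073 and 0.109 at 24 hours). With the replicate block, 8267, 7757, 8566, 7073, 9247 and 8367 genes were called, 5 and 9 lists, and odds ratios were 3.97 and 2.10. Other settings kept every count of called genes within 1.5 times, as they did the list counts at 12 and 24 hours where lists were tested again. Lists were not tested again after centring, with the robust trended eBayes or without cross-hybridising probe set types. An estimated correlation took the lists called from 15 to 4 for the difference and from 8 to 5 over time in HFM. The class term gave 355 higher and 94 lower genes of at least 2-fold at 12 hours (255 and 31 without it) and 553 and 107 over time in GM (506 and 55 without it). The odds ratio of higher genes was 6.20 without a filter and that of lower genes 1.38 with the class term. Centring moved the share of higher genes among calls from 35.4% to 58.6% at 24 hours, 39.2% to 52.0% over both times, 36.8% to 61.8% for the difference and 31.8% to 57.5% over time in HFM, quantile normalisation from 36.8% to 47.4% for the difference, and the class term from 42.0% to 52.8% over time in GM. Of 220 named results, 29 were weaker, stronger or reversed in some setting. Reversed values were 0.17 for NDUFS7 at 24 hours (adjusted p = 0.027) and 0.26 for RBM14 over time in GM (adjusted p = 0.092) without cross-hybridising probe set types, which takes another probe set, and 0.17 for MT2A at 24 hours after centring (adjusted p = 0.0013). Genes that reached log2 4 on fewer than 3 arrays were not tested. Tested genes may still lie under log2 4 on other arrays, where signal over background limits their values. Genes named as list members had no minimum level beyond this filter.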

Other observations

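The gene families below were chosen after seeing the data, and their names were matched by symbol. At 24 hours in HFM, 61 of 76 mitochondrial ribosomal protein genes fell and 0 rose, with a median of -0.37 (camera adjusted p = 2.3e-07 over 7 families; adjusted p = 0.32 with an estimated correlation), and after centring each array 49 fell and 6 rose. Proteasome subunits, which form the main protease of the cytosol, had 30 of 36 falls and 1 rise, with a median of -0.33 (adjusted p = 0.00014; adjusted p = 0.32 with an estimated correlation), and 20 falls and 2 rises after centring. These falls went with the larger 3' to 5' difference of ACTB and GAPDH in HFM at 24 hours.

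HLA genes, which encode antigen-presenting molecules, had 12 of 17 falls and 0 rises at 12 hours (median -0.33, camera adjusted p = 0.0031; adjusted p = 0.69 with an estimated correlation) and 10 rises and 0 falls at 24 hours (median 0.26, adjusted p = 0.001; adjusted p = 0.24 with an estimated correlation), with the same directions after centring. From 12 to 24 hours, 15 of 17 HLA genes fell and 0 rose in GM (median -0.56). In HFM over the same time 1 fell and 3 rose (median 0.02). The change of sign between times thus went with a fall in GM more than with a rise in HFM. The falls in HFM at 12 hours and in GM over time were both measured against the GM arrays at 12 hours. Those arrays were all of the higher hybridisation control class. A change with time in GM therefore cannot be told apart from a deviation of those arrays. HLA genes are similar in sequence, so probe sets may be shared between them, a point not tested here. Small nucleolar RNA host genes had 6 of 7 rises and 1 fall at 24 hours, with a median of 0.64 (adjusted p = 0.0018; adjusted p = 0.24 with an estimated correlation). Core and linker histone genes had 15 of 32 rises and 6 falls at 24 hours (adjusted p = 0.0016; adjusted p = 0.24 with an estimated correlation). HFM at 12 hours set directly against GM at 24 hours gave 4733 called genes in limma, 2887 higher and 1846 lower in HFM at 12 hours, and 34 of them differed by at least 2-fold.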
